A study of Mus musculus with 8 samples.

How the data were processed

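Gene expression was measured with 1-colour oligonucleotide arrays in 4 zones of the mouse tibial growth plate. The zones were the resting (RZ), proliferating (PZ), maturing (MZ) and hypertrophic zone (HZ), each taken from the same 2 mice at 9 days of age, so the series has 8 arrays and n = 2 mice per zone. Per the labels' protocols, both tibias were frozen, each zone was cut out by laser microdissection, and its RNA was extracted with Isogen. Per the labels' protocols, the RNA was amplified in 2 rounds of in vitro transcription and labelled with biotin in the second round. The labels give no sex, litter, array date or RNA quality for the mice.

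The values used were the authors' deposited signal intensity values, 1 per probe set and array, made with MAS5 per the submitters' processing notes, which state no version. They are linear: 2% trimmed means were 100 on each of the 8 arrays, so the authors had scaled the arrays to a common mean. The submitters' notes name no background or scaling setting, and detection calls were not among the values. Median signals lay between 20.2 and 26.8 and the highest signals between 5715 and 9915, while at most 0.011% of the values of an array were 0. The number of arrays limits the precision, and whether bright signals were compressed was not tested. Of 45101 probe sets, 64 controls were left out, which left 45037. The table of probe sets and genes gave 34945 of these exactly 1 gene symbol, 932 several and 9160 none. Of the 34945, 34741 were matched through their Entrez identifiers to a gene table of assembly GRCm38.p6 and took its symbol, whether or not it differed. That table was used for names alone. A gene was represented by its probe set with the highest mean signal among those with 1 symbol, which gave 18194 genes. Pthlh, Ccnb1, Runx2, Spp1 and Hbb-b1 had no such probe set and were not analysed here.

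Values were kept on the deposited scale because the trimmed means lay within 10% of each other. They were tested as log2(value + 7), where 7 is the 25th percentile of all values rounded to 1 digit. Genes were tested where their probe set was at or above the array's median on at least 2 of the 8 arrays, which left 12768 genes. Each gene was fitted in limma with lmFit and eBayes (trend = TRUE) over all 8 arrays with zone and mouse as terms, which leaves 3 residual degrees of freedom and 9.5 after moderation. The mouse is a block because all 4 zones came from the same animals, as the labels state. Checked on the values, the differences between the mice correlated between zones at r = 0.58 to 0.66 across genes, which are not independent replicates. Comparisons were PZ against RZ, MZ against PZ, HZ against MZ and HZ against RZ, each two-sided with Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05, and a moderated F test asked for any difference among the zones. All adjusted p-values of genes are from limma. Folds are ratios on the value + 7 scale and understate changes of dim genes. Signals are given as mean ± SD of the deposited values over n = 2 mice. Comparisons of neighbouring zones share the arrays of a zone, so opposite shifts in adjacent comparisons are not independent.

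A set of 31 gene lists was fixed before the data were examined. They cover chondrocyte matrix, resting zone markers, articular and superficial cartilage, proliferating chondrocyte regulators, DNA replication, mitosis, the Indian hedgehog and PTHrP pathway, hypertrophic chondrocyte markers, mineralization and phosphate, and glycosaminoglycan and sulfate synthesis. Further lists mark other cell types: osteoblast, osteoclast, erythroid, myeloid and lymphoid, endothelial, perichondrium and fibroblast, and skeletal muscle. The remaining lists cover hypoxia and HIF targets, glycolysis, oxidative phosphorylation, ribosomal proteins, the unfolded protein response with ER chaperones, cholesterol synthesis, lysosome and autophagy, the BMP, TGF-beta, WNT, and FGF and IGF pathways, matrix proteases and inhibitors, apoptosis and p53 targets, and immediate early and stress genes. One list symbol matched no gene. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01, trend.var = TRUE), which compares a list with all other genes, adjusted over the 31 lists of a comparison. Beside it stand the adjusted p with a correlation estimated for each list and the number of members past the gene test adjusted over the list alone. None of the 61 calls of lists held with an estimated correlation. In that form camera rests on the 3 residual degrees of freedom, while the preset form draws on all genes. Few lists can pass it here, so a call lost there does not by itself show that correlation between genes undoes the list. Estimated correlations ran from -0.056 to 0.702, and where they were high the p-values at the preset correlation can be much too small.

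Genes were named by a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls of each comparison among genes past the threshold that moved the same way in both mice. It also takes up to 4 passing members with the largest change of each list past its test (or 2 with the smallest p where none passed), a fixed set of growth plate genes in every comparison, and the 3 genes with the smallest F test p among those highest in each zone. Riken-type entries were counted without being named, and other genes that the text names were chosen after their values were seen. These are the few members that moved against their list (Gdf10, Igf1r and Cdkn1c in PZ against RZ, Dcn, Tgfbi and Omd in HZ against MZ, Vwf in HZ against RZ) and the genes of the closing part. Probe sets of 1 gene that passed in opposite directions were found for 0, 0, 13 and 69 genes in PZ against RZ, MZ against PZ, HZ against MZ and HZ against RZ, and for none of the named genes.

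The procedure was tested on simulated data with 200 of 12768 genes changed. In PZ against RZ it recovered 8% of genes changed by 0.5 on the log2 scale, 76% of those changed by 1 and 98% of those changed by 2, and 7.9% of its calls were false. The false share was 10.8% in MZ against PZ, 10.6% in HZ against MZ and 1.4% in HZ against RZ. Each share is from a single simulated run with few calls (138 to 170) and residuals independent between genes. Far more genes were called in the HZ comparisons of the real data, so these shares do not carry over to them. Alternatives covered the pseudocount (2, 20 or none), the filter, quantile normalization, array medians set equal, no block, the variance model, the choice of probe set, the arrays in the fit, other list tests, and leaving out each array in turn. Groups of 2 arrays are too small to test single arrays as outliers or to try other groupings of the samples. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.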

Results

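The growth plate is the cartilage disc of a long bone in which chondrocytes pass from a resting pool through division and maturation to hypertrophy before bone replaces them. Expression was measured on 8 arrays, 1 for each of 4 zones in each of 2 mice, and the arrays are named here by zone and mouse (RZ 1 to HZ 2). Across genes, the arrays of the same zone in the 2 mice correlated at r = 0.93 to 0.948, and genes are not independent replicates. The first principal component held 42.3% of the variance and set HZ (70.5 and 60.8) apart from the other zones (-39 to -3.6). The second held 22.8% and separated mouse 1 (18.4 to 38) from mouse 2 (-37.9 to -10.7) in every zone. The signal ratio of the 3′ to the 5′ end of Gapdh, a measure of how whole the amplified RNA was, differed between zones: in mouse 1 and mouse 2 it was 3.98 and 3.44 in RZ, 2.48 and 1.78 in PZ, 2.55 and 1.66 in MZ and 4.14 and 2.26 in HZ. For Actb the ratios were 5.46 and 7.25, 3.69 and 6.87, 5.92 and 6.08, and 4.1 and 5.07. Such a difference is confounded with the zones. The median standard error of a zone difference was 0.20 on the log2 scale.

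The first question was which genes differ most among the zones. Pappa2, a protease that cleaves IGF-binding proteins, was highest in RZ at 1565 ± 27.6 against 165.8 ± 49.8 in PZ, 17.85 ± 3.46 in MZ and 21.85 ± 5.44 in HZ (n = 2 mice, as for every signal given). Pcp4 and Srpx2 were likewise highest in RZ, at 2123 ± 8.2 and 1864 ± 59.8, against 203.8 ± 42.1 and 191.5 ± 34.5 in PZ, although Srpx2 was 733.9 ± 55.3 in HZ. The genes named here with their highest mean in PZ (Prelp, Slc26a2 and Prickle1) were set apart by their low level in HZ, not by PZ alone. Prelp, a leucine-rich proteoglycan of cartilage, was 3324 ± 118 in RZ, 3932 ± 114 in PZ, 3451 ± 55.4 in MZ and 194.2 ± 86.9 in HZ. Slc26a2, the sulfate transporter of chondrocytes, was 1365 ± 72.8, 2056 ± 57.3, 2038 ± 96.4 and 290.9 ± 7.35, and Prickle1 836.4 ± 42.1, 900.7 ± 163, 394.2 ± 66.5 and 64.6 ± 0.424. Indian hedgehog (Ihh), the signal by which maturing chondrocytes act on younger ones, was 37.65 ± 8.98 in RZ and 64.55 ± 1.91 in PZ but 941.8 ± 246 in MZ and 766 ± 288 in HZ. Enc1 was likewise as high in HZ (2123 ± 300) as in MZ (2152 ± 96), and Sgms2 was highest in MZ at 2514 ± 45.7 against 1566 ± 38 in HZ. Bmp6, Aldh1a3 (an enzyme of retinoic acid synthesis) and Ptgs2 (the inducible cyclooxygenase) were highest in HZ, at 1356 ± 66.8, 770.8 ± 15.5 and 571.6 ± 234, against 311.9 ± 38.3, 119.7 ± 9.05 and 21.95 ± 10.3 in MZ.

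By limma's F test 6653 of 12768 genes (52.1%) differed among the zones. Of these 1924 were highest in RZ, 809 in PZ, 1331 in MZ and 2589 in HZ. The adjusted p of the 12 genes named above lay between 1.25e-06 and 3.18e-06. Without the mouse as a block 1767 genes passed, and without HZ 2 the number was 4275.

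**Figure D1:**
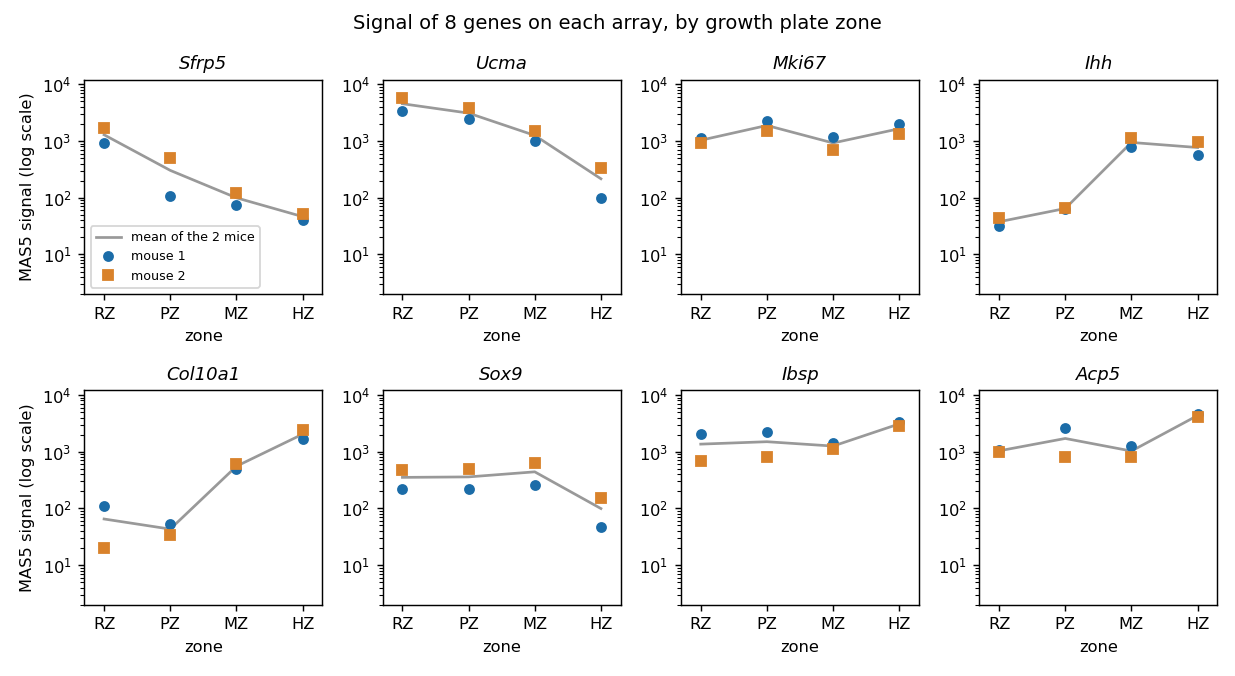
Signal (log scale) of 8 growth plate genes in the 4 zones, with circles for mouse 1, squares for mouse 2 and a line through the mean of the 2 mice. Sfrp5 and Ucma have their highest means in RZ (1285 and 4533), Ihh lies between 31.3 and 65.9 in RZ and PZ but between 562.3 and 1116 in MZ and HZ, and Col10a1 lies between 1698 and 2364 in HZ.

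The comparison of PZ with RZ asked what changes as chondrocytes leave the resting pool. Among the largest falls, Efemp1, a matrix protein of the fibulin family, went from 1580 ± 448 to 84.9 ± 1.84 (16.9-fold, adjusted p = 8.51e-05), and Omd, a keratan sulfate proteoglycan, from 1800 ± 646 to 127.5 ± 82.4 (14.4-fold, adjusted p = 0.000196). Mitosis genes as a list were higher in PZ, though not with an estimated correlation (adjusted p = 0.341). Mki67, a protein of dividing cells, rose from 1029 ± 162 to 1876 ± 513 (1.79-fold, adjusted p = 0.00952, but 0.0604, 0.0586 and 0.0542 without RZ 1, PZ 1 or PZ 2). The largest rises were smaller than the largest falls. They were led by Rhbdl2, a rhomboid protease, from 47.25 ± 14.1 to 252.2 ± 43.4 (4.83-fold, adjusted p = 0.000167). In all, 245 genes rose and 382 fell.

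Further large falls were Pcp4 and Srpx2 (10.2- and 9.5-fold), Cntn1 (13-fold), Itgbl1 (10.6-fold, with an adjusted p of 0.0513 without RZ 2) and Spock1, which dropped 13.1-fold to 10.5 ± 7.5, close to the pseudocount. Among the resting zone markers 6 of 18 tested genes fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.000143, and 0.341 with an estimated correlation). Its falls included Grem1, a BMP antagonist, Clu, Spon1 and Apoe (8.56-, 7.11-, 6.72- and 5.39-fold). The 1 member that rose was Gdf10, a BMP family member, by 1.43 on the log2 scale (adjusted p = 0.00216), and it was named after its value was seen. Sfrp5, a secreted WNT inhibitor of the resting zone, fell 5.12-fold (adjusted p = 0.0059, but 0.0589 without RZ 1 and 0.0527 without RZ 2). Ucma, another marker of upper cartilage, was 4533 ± 1720 in RZ and 3096 ± 972 in PZ, which did not pass (adjusted p = 0.225).

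The largest rises after Rhbdl2 were in Mcoln3, Fxyd2, Slc7a3, Chrdl1, Sncg, P3h2 (3.73- to 4.26-fold) and Osbp2 (4.04-fold, adjusted p = 0.0164, but 0.0572 to 0.11 without RZ 1, RZ 2, PZ 1 or PZ 2).

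The mitosis and DNA replication lists were higher in PZ, with few members past the gene test. Of 44 mitosis genes 12 rose and none fell (40 rose adjusted over the list alone, adjusted p = 2.42e-22, and 0.341 with an estimated correlation), among them Birc5 (1.89-fold) and Kif2c (1.84-fold), which act on the mitotic spindle. Birc5 lost its call without RZ 1, RZ 2 or PZ 2 (adjusted p = 0.148, 0.09 and 0.156), and Kif2c without any 1 of RZ 1, RZ 2, PZ 1 and PZ 2 (0.106 to 0.152). The DNA replication list was higher in PZ by a median of 0.31 on the log2 scale (adjusted p = 2.67e-07, and 0.348 with an estimated correlation), though none of its 34 members passed limma's test, also adjusted over the list alone. At an unadjusted p below 0.05 the number was 13, and the list's adjusted p by fry was 0.0776. Its smallest p-values belonged to Uhrf1 (144.8 ± 79.7 and 239.4 ± 143, adjusted p = 0.0564) and Pcna (1797 ± 104 and 2542 ± 644, adjusted p = 0.0911).

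The hedgehog, FGF and IGF, and TGF-beta lists were lower in PZ. In the Indian hedgehog and PTHrP pathway 4 of 14 genes fell and none rose (6 fell and 2 rose adjusted over the list alone, adjusted p = 0.00542, and 0.355 with an estimated correlation). They were the hedgehog co-receptors Boc (5.29-fold) and Cdon (1.78-fold), the hedgehog-binding protein Hhip (3.44-fold) and the transcription factor Gli2 (3.2-fold). The list's call was lost without RZ 1 (adjusted p = 0.0623), as were those of Gli2 (0.0689) and Cdon (0.137, and 0.14 without PZ 1). Ihh itself was 37.65 ± 8.98 in RZ and 64.55 ± 1.91 in PZ (adjusted p = 0.0667), and its receptor Ptch1 2187 ± 671 and 2910 ± 187 (adjusted p = 0.129). In the FGF and IGF pathway 4 of 27 genes fell and 2 rose (8 and 2 adjusted over the list alone, adjusted p = 0.0373, and 0.396 with an estimated correlation; 0.073 without RZ 1, 0.225 without PZ 2 and 0.0672 after quantile normalization). Fgfr1 fell 3.65-fold, the growth hormone receptor Ghr 3.22-fold from 1258 ± 18.7 to 385.8 ± 27.9, and its signal transducer Stat5b 2.66-fold, while Igf1r and Fgfr3 rose (by 0.76 and 0.53 on the log2 scale). Fgfr3 lost its call without any 1 of the 8 arrays (adjusted p = 0.0579 to 0.176), and Igf1r was named after its value was seen. In the TGF-beta pathway 5 of 20 genes fell and none rose (6 adjusted over the list alone, adjusted p = 0.0165, and 0.348 with an estimated correlation; 0.0793 without RZ 2). The largest falls were in Ccn2 (2.79-fold, adjusted p = 0.017, but 0.0589 to 0.0977 without RZ 1, RZ 2, PZ 1 or PZ 2) and Ltbp3, a latent TGF-beta binding protein (2.37-fold).

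The hypoxia, cholesterol synthesis, unfolded protein response and immediate early lists were higher in PZ, while glycolysis (3 genes higher and 1 lower of 15) and oxidative phosphorylation did not pass (adjusted p = 0.0862 each, and 0.0302 for the latter with array medians set equal). Of 24 hypoxia and HIF targets 6 rose (8 adjusted over the list alone, adjusted p = 1.24e-06, and 0.157 with an estimated correlation), with Car12, a carbonic anhydrase, up 3.38-fold from 644.3 ± 74.7 to 2188 ± 92.5 and Ndrg1 2.45-fold. Of 20 cholesterol synthesis genes 4 rose (8 adjusted over the list alone, adjusted p = 6.69e-09, and 0.157 with an estimated correlation), among them the enzymes Fdps (2.05-fold) and Cyp51 (2.04-fold). Of 28 genes of the unfolded protein response 6 rose (9 adjusted over the list alone, adjusted p = 4.26e-06, and 0.256 with an estimated correlation), led by Chac1 and Trib3, targets of the ATF4 arm, and by asparagine synthetase, Asns (3.09-, 2.62- and 2.37-fold). Trib3 lost its call without RZ 1, RZ 2 or PZ 2 (adjusted p = 0.0607, 0.0786 and 0.0678), Chac1 without RZ 2 or PZ 2 (0.0915 and 0.0584) and Asns without RZ 2 (0.0509). Of 24 immediate early and stress genes 3 rose (4 adjusted over the list alone, adjusted p = 0.00759, and 0.396 with an estimated correlation; 0.0551 without RZ 2 and 0.082 without PZ 1). They were Fos (1.94-fold), Ier3 and Klf4. Fos lost its call without RZ 2, PZ 1 or PZ 2 (adjusted p = 0.0857 to 0.149), Ier3 without any 1 of RZ 1, RZ 2, PZ 1 and PZ 2 (0.0537 to 0.0952), and Klf4 without any 1 of the 8 arrays (0.0534 to 0.192).

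Of 34 hypertrophic chondrocyte markers 9 rose and 2 fell (13 and 3 adjusted over the list alone, adjusted p = 1.77e-05, 0.348 with an estimated correlation and 0.0599 by fry). The rises were in Car12, in Sp7 and Dlx5, transcription factors of bone-forming cells (3.26- and 3.25-fold), and in 6 others, while Fgfr1 and Cdkn1c fell. The collagen of hypertrophy itself, Col10a1, was 65.05 ± 64.1 in RZ and 43.15 ± 12.8 in PZ (adjusted p = 0.874). Markers of other cells differed between the mice on the PZ arrays. Their mean log2 signals on PZ 1 and PZ 2 were 9.02 and 4.92 for skeletal muscle, 8.89 and 7.53 for osteoblasts, 8.57 and 7.48 for osteoclasts, 8.28 and 7.3 for perichondrium and fibroblasts, 7.72 and 6.96 for myeloid cells, 8.48 and 7.75 for erythroid cells and 6.06 and 5.37 for endothelium. The erythroid list was higher in PZ (adjusted p = 0.000143, and 0.433 with an estimated correlation), with a median difference of 1.12 in mouse 1 and 0.06 in mouse 2. Its call was lost without RZ 1 (adjusted p = 0.119). None of its 11 genes passed limma's test, 1 did adjusted over the list alone and 7 at an unadjusted p below 0.05, and the list's adjusted p by fry was 0.298. Rhag was 94.15 ± 4.17 in RZ and 169.6 ± 69.2 in PZ (adjusted p = 0.0669), and Hemgn 595 ± 191 and 1233 ± 666 (adjusted p = 0.141).

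By limma's moderated test 627 of 12768 genes differed between PZ and RZ, of which 88 rose and 221 fell more than 2-fold. All moved in the same direction in both mice, but passing with 2 mice as a block nearly requires this, so it is no separate evidence. With array medians set equal the split was 342 higher and 318 lower, 19 mitosis genes rose and 2 TGF-beta genes fell. Without the mouse as a block 25 genes passed, and without RZ 1, RZ 2, PZ 1 or PZ 2 the numbers were 259, 223, 315 and 325. Of 31 lists 8 were higher and 4 lower.

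The comparison of MZ with PZ asked what changes as chondrocytes stop dividing and mature. Genes of cell division fell together: of 44 mitosis genes 43 fell (44 adjusted over the list alone, adjusted p = 5.17e-29, and 0.202 with an estimated correlation), and of 34 DNA replication genes 24 fell (30 adjusted over the list alone, adjusted p = 9.23e-18, and 0.202 with an estimated correlation). Signals of the next stage appeared: Ihh rose 13-fold from 64.55 ± 1.91 to 941.8 ± 246 (adjusted p = 2.89e-05) and Col10a1 11.3-fold from 43.15 ± 12.8 to 553.3 ± 85.1 (adjusted p = 0.00275). The PTHrP receptor Pth1r rose 3.57-fold to 4091 ± 727 (adjusted p = 0.00112) and Mef2c, a transcription factor of hypertrophy, 3.26-fold to 1554 ± 765 (adjusted p = 0.000861).

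Among the mitosis genes Ect2, Bub1b, Bub1 and Kif2c fell 3.26-, 3.06-, 2.92- and 2.79-fold, and Mki67 fell 2.06-fold to 921.4 ± 341. Among the replication genes the helicase subunits Mcm3 and Mcm4 fell 2.42-fold (521.6 ± 49.3 to 211.6 ± 25.5) and 2.31-fold. Of 34 hypertrophic chondrocyte markers 17 rose and 1, Vegfa, fell (20 and 4 adjusted over the list alone, adjusted p = 4.1e-12, and 0.202 with an estimated correlation). They included the growth factors Bmp6 (8.13-fold) and Bmp2 (4.2-fold). Alpl, the phosphatase of mineralization, rose 3.85-fold (adjusted p = 0.0193, but 0.123 without PZ 2 and 0.179 without MZ 2). Vegfa, the angiogenic factor, fell 1.95-fold (adjusted p = 0.00954, but 0.0505 without PZ 2 and 0.111 without MZ 1). The hedgehog receptor and target Ptch1 fell 1.89-fold (adjusted p = 0.00531, but 0.0503 without PZ 2 and 0.0785 without MZ 1) while Ihh rose.

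Cholesterol synthesis genes rose further: 8 of 20 rose (15 adjusted over the list alone, adjusted p = 2.75e-10, and 0.202 with an estimated correlation), led by Msmo1 (2.46-fold to 1807 ± 96.8) and Ebp (2.13-fold to 956 ± 225). Of 28 genes of the unfolded protein response 4 rose and Trib3 fell (11 and 2 adjusted over the list alone, adjusted p = 1.39e-05, and 0.202 with an estimated correlation). Manf, a secreted ER stress protein, rose 1.68-fold (adjusted p = 0.00454, but 0.051 without MZ 1 and 0.0662 without MZ 2), and Trib3 fell 1.93-fold (adjusted p = 0.0272, but 0.119 to 0.211 without PZ 2, MZ 1 or MZ 2). Of 42 oxidative phosphorylation genes 4 rose (3 adjusted over the list alone, adjusted p = 4.5e-08, and 0.398 with an estimated correlation), by at most 1.67-fold for Atp5g1 (adjusted p = 0.00742). All 4 (Atp5g1, Uqcrq, Ndufa8 and Ndufb7) lost their call when PZ 2, MZ 1 or MZ 2 was left out.

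The largest rise was that of Cbln2, a secreted synaptic protein (21.7-fold from 6.75 ± 7.42, close to the pseudocount, to 299.8 ± 190). After Ihh and Col10a1 followed Prom1 (9.7-fold), Fxyd3 (9.11-fold), the matrix protein Spon2 (8.94-fold) and Enc1 (8.71-fold). The largest falls were in Pla2g7, Lrrn1, Pappa2, Ppp1r3c, C1s1, Adamts20, Smoc1 and Mamdc2 (4.55- to 7.11-fold), among which Ppp1r3c, a glycogen-targeting phosphatase subunit, went from 1245 ± 76.2 to 237.6 ± 51.7. The matrix genes Col2a1 (5912 ± 1260 and 6910 ± 2150) and Acan (5108 ± 1090 and 5839 ± 1500) did not pass (adjusted p = 0.45 and 0.528). The skeletal muscle list had a median difference of -1.53 in mouse 1 and 1.79 in mouse 2, and the osteoclast list of -0.86 and -0.04. Neither passed on the deposited scale (adjusted p = 0.384 and 0.0797), but the osteoclast list was called lower after quantile normalization (0.0372) and with array medians set equal (0.0351).

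By limma's moderated test 623 genes rose and 891 fell in MZ against PZ, 1514 in all, of which 215 and 352 changed more than 2-fold. All moved in the same direction in both mice, which the test nearly requires. With array medians set equal the split was 1128 higher and 582 lower, as this scaling moved the median of all genes from -0.08 to 0.07 on the log2 scale. Without the mouse as a block 20 genes passed, and without PZ 1, PZ 2, MZ 1 or MZ 2 the numbers were 734, 802, 421 and 413. With array medians set equal 14 cholesterol synthesis, 11 unfolded protein response and 8 oxidative phosphorylation genes rose, and after quantile normalization 9, 3 and 2. Of 31 lists 4 were higher and 2 lower, against 10 lists without PZ 1 and 15 without PZ 2.

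The comparison of HZ with MZ asked what sets the end stage of the growth plate, next to bone and its vessels, apart from maturing cartilage. Many cartilage genes fell: Prelp went from 3451 ± 55.4 to 194.2 ± 86.9 (18-fold, adjusted p = 1.71e-05), Sox9, the master transcription factor of chondrocytes, from 441 ± 252 to 99.35 ± 73.6 (4.43-fold, adjusted p = 2.98e-05), and Slc26a2 6.86-fold (adjusted p = 1.71e-05). Markers of the vessel wall, of osteoclasts and of myeloid cells were higher as lists, though not with an estimated correlation (adjusted p = 0.267, 0.325 and 0.325). Rises included the VEGF receptor Kdr from 87.8 ± 51.1 to 769.2 ± 195 (8.71-fold, adjusted p = 3.02e-05) and Acp5, the tartrate-resistant phosphatase of osteoclasts, from 1026 ± 315 to 4335 ± 411 (4.3-fold, adjusted p = 0.000673). Ptgs2 showed the largest rise on the value + 7 scale, 19.8-fold to 571.6 ± 234 (adjusted p = 1.71e-05). In all, 2865 genes rose and 2082 fell.

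Of 30 chondrocyte matrix genes 26 fell and 1, Dcn, rose (27 and 1 adjusted over the list alone, adjusted p = 1.58e-12, and 0.161 with an estimated correlation). Scrg1 (10.6-fold), Ucma (6.49-fold) and Sox5 (6.17-fold) fell with Prelp, while the 2 main components Col2a1 (6910 ± 2150 and 5270 ± 1220, adjusted p = 0.0913) and Acan (5839 ± 1500 and 4867 ± 1480, adjusted p = 0.237) did not pass. Of 21 genes of glycosaminoglycan and sulfate synthesis 10 fell and 2 rose (the same numbers adjusted over the list alone, adjusted p = 8.34e-05, and 0.156 with an estimated correlation), and the chondroitin sulfation enzyme Chst11 fell 4.04-fold to 974.1 ± 248. Of 15 proliferating chondrocyte regulators 9 fell and 2 rose (the same numbers adjusted over the list alone, adjusted p = 0.00287, and 0.325 with an estimated correlation), with Sox9, Igf1r (2.96-fold) and Trpv4 (2.6-fold) among the falls. Mycn rose 3.39-fold (adjusted p = 0.00823, but 0.0912 without MZ 2 and 0.108 without HZ 2). Other large falls were in Gdf10, H2-DMa, Il17b, Ddn and Fbln7 (7.9- to 9.85-fold).

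The glycolysis, cholesterol synthesis, ribosomal protein, hypoxia and unfolded protein response lists were lower in HZ. Of 15 glycolysis genes 13 fell (13 adjusted over the list alone, where 1 also rose, adjusted p = 1.96e-08, and 0.124 with an estimated correlation), including the lactate transporter Slc16a3 (6.6-fold), Aldoc (4.06-fold) and Pgam1 (2.75-fold). Of 20 cholesterol synthesis genes 17 fell (18 adjusted over the list alone, adjusted p = 1.31e-10, and 0.124 with an estimated correlation), with Msmo1 down 4.03-fold to 444 ± 45.1. Of 32 ribosomal protein genes 25 fell (30 adjusted over the list alone, adjusted p = 3.28e-09, and 0.325 with an estimated correlation), led by Rpl37 (2.58-fold). After quantile normalization 5 of them fell, and the list's median went from -0.50 to -0.08. Of 42 oxidative phosphorylation genes 15 fell and 2 rose (18 and 3 adjusted over the list alone, adjusted p = 0.000124, and 0.325 with an estimated correlation). After quantile normalization, however, 2 fell and 4 rose and the direction turned (adjusted p = 0.513), while with array medians set equal 33 fell. Of 24 hypoxia and HIF targets 17 fell and 5 rose (the same numbers adjusted over the list alone, adjusted p = 1.35e-05, and 0.151 with an estimated correlation). The carbonic anhydrase Car9 (3.69-fold) and Pdk1, a brake on pyruvate oxidation (3.66-fold), fell, while Epas1, the transcription factor HIF-2 alpha, and the vasodilator Adm rose (6.02- and 3.98-fold). Of 28 genes of the unfolded protein response 16 fell and 3 rose (17 and 3 adjusted over the list alone, adjusted p = 0.000103, and 0.186 with an estimated correlation). Creb3l2 fell 2.57-fold and Asns 2.07-fold, whereas the sensor Atf6 and Ddit3, a factor of stress-induced cell death, rose 2.27-fold each (Ddit3 not without MZ 1, adjusted p = 0.124, or HZ 1, 0.0921).

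Lists of markers of the bone and marrow side were higher in HZ. Of 19 endothelial markers 18 rose (18 adjusted over the list alone, adjusted p = 2.1e-09, and 0.267 with an estimated correlation), with Sox18 up 15.3-fold from 31.05 ± 15.5 to 599.7 ± 336 and Mmrn2 7.26-fold. Of 14 osteoclast markers 13 rose (14 adjusted over the list alone, adjusted p = 2.5e-07, and 0.325 with an estimated correlation), such as the fusion protein Ocstamp (12-fold to 765 ± 70.4) and integrin beta 3, Itgb3 (11.1-fold to 1423 ± 234). Of 26 myeloid and lymphoid markers 18 rose (21 adjusted over the list alone, adjusted p = 7.57e-08, and 0.325 with an estimated correlation), including Cd68 (8.2-fold) and Tyrobp (5.94-fold). Of 22 perichondrium and fibroblast markers 8 rose (9 rose and 1 fell adjusted over the list alone, adjusted p = 0.012, and 0.418 with an estimated correlation), led by Cd34 and Thy1 (9.13- and 7.53-fold). Of 11 erythroid markers 4 rose (7 adjusted over the list alone, adjusted p = 0.0251, and 0.507 with an estimated correlation; 0.163 without MZ 2 and 0.0759 without HZ 2). Each of the 4 (Ermap, Rhag, Gata1 and Hbb-b2) lost its call without MZ 2, HZ 1 or HZ 2 (adjusted p = 0.0595 to 0.313). With array medians set equal each of the 4 lost its call, though the list was called (adjusted p = 0.014). With the mean over a gene's probe sets Hbb-b2 turned to -0.10 on the log2 scale (adjusted p = 0.828). Skeletal muscle markers went the other way: 2 of 17 fell, Tnni2 (3.39-fold) and Tnnt3, the latter not without MZ 2 (adjusted p = 0.156) or HZ 2 (0.169) (the same number adjusted over the list alone, adjusted p = 0.0242, and 0.554 with an estimated correlation), with a median of -0.18 in mouse 1 and -1.74 in mouse 2. This list's call was lost without MZ 2 (0.737), without the block (0.0864) and with array medians set equal (0.0963).

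The mineralization and osteoblast lists were higher in HZ. Of their tested genes 11 of 13 and 10 of 16 are also in another list, as are 23 of 34 hypertrophic chondrocyte markers and 9 of 18 resting zone markers. Calls of these lists, here and in the other comparisons, are thus not independent of each other. Of 13 mineralization and phosphate genes 9 rose and 2 fell (the same numbers adjusted over the list alone, adjusted p = 0.0168, and 0.418 with an estimated correlation; 0.0578 without HZ 2), with Dmp1, a matrix protein of osteocytes, up 8.07-fold to 747.6 ± 17.7 and the pyrophosphate transporter Ank 5.18-fold to 832.4 ± 70.8. Of 16 osteoblast markers 7 rose and 1, Omd, fell (the same numbers adjusted over the list alone, adjusted p = 0.0355, and 0.507 with an estimated correlation). Cdh11 rose 7.71-fold and Cpz 4.72-fold, and the list's call was lost without RZ 1, RZ 2, MZ 1 or HZ 2 (0.0556, 0.0561, 0.0844 and 0.152). Col10a1 rose a further 3.61-fold to 2031 ± 471 (adjusted p = 0.0152, but 0.163 without MZ 1 and 0.19 without HZ 2). Mmp13, the collagenase of hypertrophic cartilage, rose 2.65-fold (adjusted p = 0.00598, but 0.0538 without MZ 2 and 0.0922 without HZ 2) and Ibsp 2.46-fold (adjusted p = 0.00878, but 0.117 without MZ 1 and 0.127 without HZ 2). Ihh was 941.8 ± 246 in MZ and 766 ± 288 in HZ (adjusted p = 0.204). The list of hypertrophic chondrocyte markers, with 12 higher and 11 lower of 34, did not pass (adjusted p = 0.535), and its median (-0.08) and test pointed down while its mean (0.19) was above 0. After quantile normalization 15 were higher and 7 lower (median 0.17), and with array medians set equal 10 and 14 (median -0.33). The list passed under neither scaling.

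A further 8 lists were higher in HZ than in MZ, whereas the Indian hedgehog and PTHrP list (3 genes higher and 3 lower of 14) did not pass (adjusted p = 0.931). Of 23 matrix proteases and inhibitors 17 rose (17 rose and 1 fell adjusted over the list alone, adjusted p = 5.62e-06, and 0.186 with an estimated correlation), including Mmp10 (9.85-fold), heparanase, Hpse (7.81-fold to 685.8 ± 150), and the heparan sulfatase Sulf1 (7.14-fold). Of 24 immediate early and stress genes 16 rose and 1 fell (the same numbers adjusted over the list alone, adjusted p = 6.42e-05, and 0.263 with an estimated correlation), with Egr1 up 8.01-fold and Dusp1 7.33-fold. Of 20 TGF-beta pathway genes 12 rose and Tgfbi fell (13 and 1 adjusted over the list alone, adjusted p = 0.00113, and 0.186 with an estimated correlation), with Ccn2 and Tgfb3 up 4.83- and 4.6-fold. Of 27 FGF and IGF pathway genes 15 rose and 5 fell (the same numbers adjusted over the list alone, adjusted p = 0.037, and 0.325 with an estimated correlation; 0.0759 without HZ 2), with Igfbp3 up 16.2-fold to 362.5 ± 115 and Dusp6 10.1-fold. Of 20 apoptosis and p53 targets 8 rose and 1 fell (the same numbers adjusted over the list alone, adjusted p = 0.0277, and 0.263 with an estimated correlation), led by Trp53inp1 (6.15-fold). Of 18 resting zone markers 9 rose and 2 fell (10 and 3 adjusted over the list alone, adjusted p = 0.0334, and 0.325 with an estimated correlation; 0.0618 without MZ 2 and 0.0985 without HZ 2). The falls were Gdf10 and Ucma, and the rises included Wif1, a WNT inhibitor (6.85-fold), and Pdgfra, a receptor of mesenchymal cells (5.97-fold). Of 44 mitosis genes 25 rose (26 adjusted over the list alone, adjusted p = 1.03e-05, and 0.329 with an estimated correlation) and of 34 DNA replication genes 22 (24 rose and 1 fell adjusted over the list alone, adjusted p = 1.47e-05, and 0.325 with an estimated correlation), such as Bub1b (2.27-fold) and Mcm3 (2.12-fold), beside the rise of the marrow and vessel markers. These numbers were 14 and 17 after quantile normalization and 11 and 14 with array medians set equal, where 2 replication genes also fell.

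Further genes with the largest rises were Slit3, Kcne3, Mcam, Plk2 and Depp1 (14.8- to 17.1-fold). By limma's moderated test 4947 of 12768 genes differed between HZ and MZ, of which 1580 rose and 643 fell more than 2-fold. All moved in the same direction in both mice, which the test nearly requires. With array medians set equal the split was 1963 higher and 3366 lower, as this scaling moved the median of all genes from 0.06 to -0.19 on the log2 scale. Without the mouse as a block 1646 genes passed, and without MZ 1, MZ 2 or HZ 2 the numbers were 2902, 3281 and 2741. Of 31 lists 15 were higher and 10 lower.

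**Figure D2:**
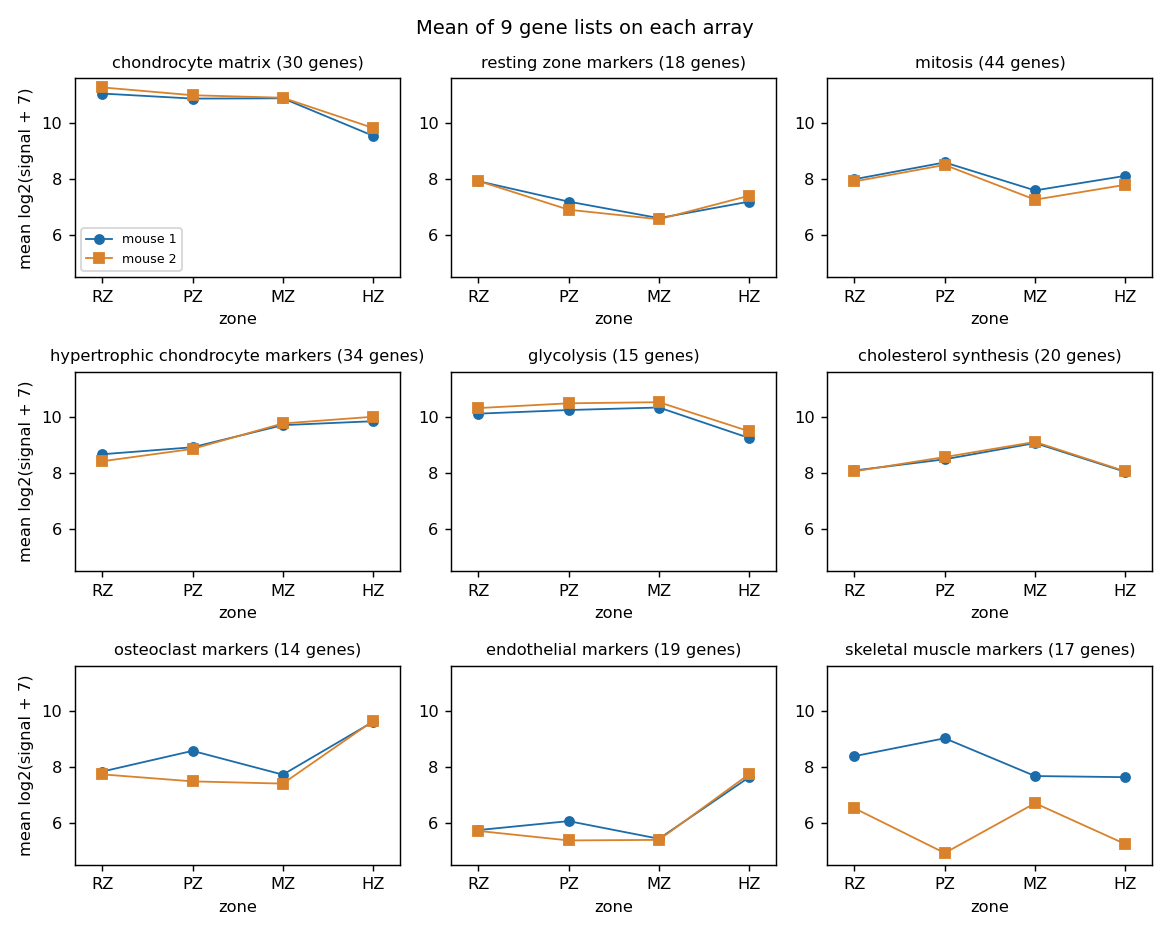
Mean log2(signal + 7) of 9 gene lists on each array by zone, with circles for mouse 1 and squares for mouse 2 joined by lines. Chondrocyte matrix and glycolysis are lowest in HZ, mitosis is highest in PZ, cholesterol synthesis peaks in MZ, osteoclast and endothelial markers are highest in HZ, and skeletal muscle markers lie between 4.92 and 9.02, higher in mouse 1 in each zone.

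The comparison of HZ with RZ set the ends of the growth plate against each other. Ptgs2 rose 48.2-fold from 5 ± 4.81, under the pseudocount, to 571.6 ± 234 (adjusted p = 1.36e-06), Col10a1 35.9-fold from 65.05 ± 64.1 to 2031 ± 471 (adjusted p = 6.26e-05) and Bmp6 34.7-fold from 32.25 ± 1.48 to 1356 ± 66.8 (adjusted p = 5.96e-07). Pappa2 fell 55-fold (adjusted p = 5.96e-07), Pcp4 50.9-fold, Efemp1 43-fold, Sfrp5 23.3-fold and Ucma 23-fold from 4533 ± 1720 to 215.6 ± 164 (adjusted p = 2.2e-06). Penk, the precursor of enkephalins, fell 30.5-fold from 3388 ± 397 to 109.2 ± 49.4, and Scube2, a secreted partner of hedgehog release, 31.7-fold. In all, 2575 genes rose and 2648 fell.

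Of 34 hypertrophic chondrocyte markers 24 rose and 2 fell (the same numbers adjusted over the list alone, adjusted p = 8.57e-09, and 0.254 with an estimated correlation), with Ihh up 16.9-fold and Bmp2 14.6-fold beside Col10a1 and Bmp6. Of 13 mineralization genes 10 rose and 1 fell (the same numbers adjusted over the list alone, adjusted p = 0.000966, 0.425 with an estimated correlation and 0.0635 by fry), including Phex (13.6-fold), Dmp1 (10.4-fold) and Alpl (5.79-fold to 1735 ± 447). Of 16 osteoblast markers 11 rose and Omd fell (11 and 2 adjusted over the list alone, adjusted p = 0.00499, 0.476 with an estimated correlation and 0.153 by fry). Of 20 apoptosis and p53 targets 11 rose (11 adjusted over the list alone, adjusted p = 0.000895, and 0.254 with an estimated correlation), with the cell cycle inhibitor Cdkn1a up 6.85-fold to 2305 ± 302. Of 24 immediate early genes 18 rose (20 adjusted over the list alone, adjusted p = 4.79e-08, and 0.254 with an estimated correlation), with Atf3 up 18.8-fold and Fos 5.17-fold. Of 23 matrix proteases and inhibitors 15 rose and 2 fell (the same numbers adjusted over the list alone, adjusted p = 3.79e-05, and 0.286 with an estimated correlation), with Hpse up 13.2-fold. Of 25 lysosome and autophagy genes 10 rose and 2 fell (the same numbers adjusted over the list alone, adjusted p = 0.0251, and 0.425 with an estimated correlation; 0.0523 without RZ 2 and 0.0737 without HZ 2), with cathepsin H, Ctsh, up 2.39-fold. Large rises outside these lists were in Aldh1a3 (23.3-fold), the natriuretic peptide receptor Npr3 (21.7-fold), Cds1 (18.9-fold) and the collagen cross-linking enzyme Loxl4 (17.5-fold).

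Of 30 chondrocyte matrix genes 26 fell (26 adjusted over the list alone, adjusted p = 9.03e-11, and 0.254 with an estimated correlation), among them Scrg1 (21-fold), Prelp (17.4-fold) and Sox5 (9.93-fold). Of 15 proliferating chondrocyte regulators 11 fell and Pth1r rose (11 and 2 adjusted over the list alone, adjusted p = 0.000287, and 0.352 with an estimated correlation), with Snai2 down 3.33-fold and Igf2 3.28-fold. Of 21 genes of glycosaminoglycan synthesis 11 fell and 4 rose (the same numbers adjusted over the list alone, adjusted p = 0.0191, and 0.288 with an estimated correlation), with Csgalnact1 down 4.35-fold. Of 15 glycolysis genes 12 fell (12 adjusted over the list alone, adjusted p = 5.98e-06, and 0.254 with an estimated correlation), including Aldoc (3.12-fold) and Pfkp (2.73-fold). Of 32 ribosomal protein genes 26 fell (30 adjusted over the list alone, adjusted p = 2e-07, and 0.425 with an estimated correlation), led by Rpl37 (3.31-fold). After quantile normalization 10 of them fell, and the list's median went from -0.50 to -0.13. Of 24 hypoxia and HIF targets 13 fell and 5 rose (13 and 6 adjusted over the list alone, adjusted p = 0.0478, and 0.348 with an estimated correlation), with Car9 down 10.3-fold and Adm up 9.14-fold. This list's call was lost without PZ 1, PZ 2, MZ 1, MZ 2 or HZ 2 (adjusted p = 0.0556 to 0.0619), without the block (0.11) and with array medians set equal (0.0518).

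Markers of other cells that passed followed the same directions as in HZ against MZ, while the perichondrium and fibroblast list (8 higher and 5 lower of 22) did not pass (adjusted p = 0.191). Of 19 endothelial markers 17 rose and Vwf fell (18 and 1 adjusted over the list alone, adjusted p = 8.57e-09, and 0.348 with an estimated correlation), with Kdr up 8.73-fold. Of 14 osteoclast markers 13 rose (13 adjusted over the list alone, adjusted p = 2e-07, and 0.397 with an estimated correlation), with Acp5 up 4.17-fold. Of 26 myeloid and lymphoid markers 17 rose and 2 fell (22 and 2 adjusted over the list alone, adjusted p = 2.24e-06, and 0.425 with an estimated correlation), with Lcp1 up 4.24-fold. Of 11 erythroid markers 10 rose (10 adjusted over the list alone, adjusted p = 0.000287, 0.425 with an estimated correlation and 0.0635 by fry), with Rhag up 2.5-fold. Of 17 skeletal muscle markers 3 fell (1 adjusted over the list alone, adjusted p = 0.0371, and 0.696 with an estimated correlation; 0.153 without RZ 2, 0.0659 without HZ 1 and 0.164 without the block), and Tnni2 fell 14.1-fold from 3602 ± 338 to 270.4 ± 155.

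By limma's moderated test 5223 of 12768 genes differed between HZ and RZ, of which 1357 rose and 1110 fell more than 2-fold. All moved in the same direction in both mice, which the test nearly requires. Of 31 lists 11 were higher and 7 lower. Without the mouse as a block 1843 genes passed, and without HZ 2 the number was 2825.

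A further 3 lists passed in none of the 4 comparisons, namely the BMP pathway (adjusted p = 0.4, 0.313, 0.541 and 0.191 in PZ against RZ, MZ against PZ, HZ against MZ and HZ against RZ), the WNT pathway (0.395, 0.679, 0.127 and 0.573) and articular and superficial cartilage (0.142, 0.558, 0.253 and 0.576). Members moved in both directions, such as Bmp6 and Grem1 in the BMP list. In HZ against RZ 10 of 27 BMP genes rose and 6 fell, as did 9 and 12 of 30 WNT genes. A list split in this way can miss camera's test. By fry the WNT list passed in PZ against RZ, HZ against MZ and HZ against RZ (adjusted p = 0.0377, 0.0246 and 0.00696). The BMP list passed by fry in HZ against MZ and HZ against RZ (0.0253 and 0.00383), and the articular list in no comparison. The DNA replication and mitosis lists, called in each neighbouring comparison, did not pass in HZ against RZ (adjusted p = 0.624 and 0.827), where 5 and 1 genes rose and 4 and 5 fell. Median, mean and test differed in sign for lists without a call: endothelial, fibroblast, BMP and protease lists in PZ against RZ, and chondrocyte matrix, mineralization, osteoblast, BMP, WNT, apoptosis and immediate early lists in MZ against PZ. The same held for the oxidative phosphorylation, cholesterol synthesis, and FGF and IGF lists in HZ against RZ.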

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

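All tests in this part were chosen after the results they address were seen. Their bootstrap and Wilson intervals take the genes of a list as units, although these genes move together. The intervals thus measure the spread among genes, not that between arrays or animals.

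The skeletal muscle markers moved in opposite directions in the 2 mice. Their median difference of PZ against RZ was 0.91 on the log2 scale in mouse 1 and -1.74 in mouse 2, and that of MZ against PZ was -1.53 in mouse 1 and 1.79 in mouse 2. The difference between the mice was not tested, as each has 1 array per zone. Of 124 combinations of a list and a comparison, 20 had medians of opposite sign in the mice, and these 2 alone reached 0.5 in both mice, a minimum chosen after the data were seen.

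Muscle transcripts were brighter in mouse 1 (median difference 2.49 over 17 genes in the mean of the zones, 4.22 in PZ and 0.76 in MZ). In the scaled values this difference was not shared by all genes, whose median was -0.04. The muscle list stood 2.53 above that median (95% bootstrap interval 1.89 to 2.91, 10000 draws). Scaling the arrays to a common trimmed mean largely fixes the median of all genes, so a shift of all genes before scaling was not tested. Skeletal muscle taken up with the tissue of mouse 1 stays open, since 16 of 17 genes (94.1%) being higher in mouse 1 restates the pattern and neither excludes nor supports it. The most abundant were Tnni2 (829.7 ± 386 in PZ), Tnnc2 (1199 ± 1630) and Acta1 (1132 ± 1530), 0 of the 17 are in another list, and 6 of 17 were above the median on each of the 6 RZ, PZ and MZ arrays. Laser microdissection selects by position and no sort by cell type was applied, and a difference between the animals themselves stays open, untested.

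Markers of osteoclasts, endothelium and myeloid cells were higher in HZ than in MZ. A lower share of chondrocyte RNA that raised all other cell types alike stays open. The markers' median change exceeded that of skeletal muscle by 1.98 in mouse 1 (95% bootstrap interval 1.37 to 2.32) and by 3.74 in mouse 2 (2.82 to 4.17). Muscle signal itself varied between the arrays of a zone, with list means of 7.67 and 6.7 on MZ 1 and MZ 2 and 7.63 and 5.24 on HZ 1 and HZ 2. Muscle therefore cannot stand for all other cell types. Cells of the bone and marrow side taken up with the HZ tissue are a candidate source that cannot be told apart from expression by the zone's own cells: of the erythroid markers, a marrow list outside the pattern, 10 of 11 (90.9%, 95% Wilson interval 62.3 to 98.4) were higher in HZ in both mice against 43% of all genes, but the most abundant, Alas2, Slc4a1 and Hemgn, did not pass (adjusted p = 0.126, 0.125 and 0.133). The most abundant markers rose from MZ to HZ for osteoclasts (Ctsk 2156 ± 238 to 5071 ± 1300, Mmp9 1396 ± 136 to 5545 ± 1220) and endothelium (Kdr 87.8 ± 51.1 to 769.2 ± 195, Plvap 87.25 ± 31.5 to 612.8 ± 70.8), whereas of the myeloid ones Csf1r rose (677.6 ± 97.8 to 2933 ± 55.9) and Ngp and S100a9 did not pass (adjusted p = 0.133 and 0.0998). Of the lists' members, 12 of 14 osteoclast, 12 of 19 endothelial and 20 of 26 myeloid markers were above the array median on all 6 RZ, PZ and MZ arrays and 1, 2 and 0 are in another list, and the microdissection, which selects by position, had no sort that would remove other cells.

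Mitosis and DNA replication genes were higher in HZ than in MZ by a median of 0.61 on the log2 scale (95% bootstrap interval 0.45 to 0.7, 78 genes). The scaling of the arrays as the whole cause was argued against, as the median stayed at 0.36 (0.2 to 0.45) with array medians set equal and at 0.46 (0.39 to 0.55) after quantile normalization. Proliferating chondrocytes carried into the HZ tissue as the whole cause were argued against too: the median cell cycle gene would need 48.1% of PZ tissue (38.5 to 53.8), while Prelp, Ucma and Scrg1, chosen as the lowest of 22 abundant matrix genes because carried tissue brings them all, stood in HZ at 4.9%, 7% and 7.6% of their PZ signal (Col2a1 and Acan, at 5270 and 4867 in HZ against 5912 and 5108 in PZ, set no such limit). Dividing cells of the marrow side taken up with the tissue may explain the 0.61 but cannot be told apart from a change in the zone's own cells. The osteoclast, endothelial and myeloid lists rose with the cell cycle genes in both mice. Against RZ, whose own cells may divide at another rate, those 3 lists were higher in HZ too. Mitosis and DNA replication did not pass there (medians 0.08 and 0.03, adjusted p = 0.827 and 0.624 by camera). From RZ to PZ the 3 lists rose in mouse 1 (by 0.81, 0.38 and 0.64) but had medians of -0.23, -0.39 and -0.08 in mouse 2. Mitosis rose there in both mice (0.58 and 0.63).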

How the results depend on the processing

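The alternatives were fixed before the data were examined, except the list tests with array medians set equal, which were chosen after seeing the data. None of them was left out. With either other pseudocount or none, with any of 3 other filters, after quantile normalization, with array medians set equal, with robust eBayes or with the mean over probe sets, the 4 counts of genes and the count for any zone difference stayed within 1.5 times their value in the report. The 4 counts did so too with the arrays of the 2 zones alone, a setting that gives no count for any zone difference.

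The mouse as a block, which pairs the zones of an animal, changed all 5 counts of genes. Without it 25 genes passed in PZ against RZ, 20 in MZ against PZ, 1646 in HZ against MZ, 1843 in HZ against RZ and 1767 for any zone difference, since the differences between the mice (4501 genes) then stay in the residual spread. The eBayes fit without a trend gave 276 genes in PZ against RZ and 923 in MZ against PZ, and the cause was not tested. Testing all 26215 probe sets singly gave 7928 in HZ against MZ, 9321 in HZ against RZ and 11534 for any zone difference, because more features were tested.

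With a correlation estimated for each list, camera called 0 lists in each of the 4 comparisons. At an unadjusted p below 0.05 the numbers were then 4, 5, 8 and 5 lists in PZ against RZ, MZ against PZ, HZ against MZ and HZ against RZ, and the smallest adjusted p-values 0.157, 0.202, 0.124 and 0.254. This form of camera rests on the 3 residual degrees of freedom. In HZ against MZ the adjusted p of glycolysis went from 1.96e-08 to 0.124, although its estimated correlation (-0.056) was below the preset 0.01. A call lost in this form therefore does not by itself decide whether a list is shifted. Glycolysis had the lowest estimate, however. Others were far above the preset: 0.287 for mitosis, 0.401 for endothelial, 0.492 for myeloid, 0.589 for osteoclast, 0.622 for ribosomal protein, 0.664 for skeletal muscle and 0.702 for erythroid genes. For such lists the p-values at the preset correlation can be much too small. Limma's fry, which asks whether a list's genes move one way without comparing them with other genes, called 9, 6, 24 and 19 lists. In MZ against PZ camera called 10 lists after quantile normalization and 13 with array medians set equal, against 6 in the report, and the cause was not tested. Lists that gained a call under both scalings there were osteoclast markers, TGF-beta, and FGF and IGF (adjusted p = 0.0248 to 0.0479, each lower in MZ). In the other comparisons quantile normalization added lysosome and autophagy in HZ against MZ (0.000944) and the hedgehog list (0.0407, lower) and oxidative phosphorylation (0.0152, higher) in HZ against RZ, and equal medians added oxidative phosphorylation in PZ against RZ (0.0302). Of 61 calls of lists, 58 remained without the block, 59 after quantile normalization, 59 with array medians set equal, 61 without a pseudocount, 61 without a filter and 47 by fry. Lost by fry in PZ against RZ were DNA replication, hypertrophic chondrocyte, erythroid, FGF and IGF, and immediate early genes (adjusted p = 0.0599 to 0.298). In MZ against PZ it was oxidative phosphorylation (0.0799). In HZ against MZ and HZ against RZ alike they were mineralization, osteoblast, erythroid and skeletal muscle genes (0.0635 to 0.424).

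Of 346 gene results that the naming rule gave (226 genes), 307 were called. Of these 178 remained without the block (14 of 55, 8 of 44, 83 of 117 and 73 of 91 in the 4 comparisons in the order above), 274 in eBayes without a trend, 274 with the mean over probe sets and 292 to 306 with the other settings in which all 307 had a value. The stricter filter left 288, all of which kept their call, and the filter on the mean 273, of which 272 did. In every alternative other than leaving out an array 171 kept their call. Reversals were found for Hbb-b2 in HZ against MZ with the mean over probe sets (-0.10 on the log2 scale, adjusted p = 0.828) and for the oxidative phosphorylation list in HZ against MZ after quantile normalization (adjusted p = 0.513, 2 genes lower and 4 higher), and the cause was not tested.

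Leaving out each array in turn leaves a zone with 1 array, which is assumed to vary like the others, and 1 residual degree of freedom less. The counts then ranged from 223 to 428 in PZ against RZ (lowest without RZ 2), from 413 to 1565 in MZ against PZ (without MZ 2), from 2741 to 5062 in HZ against MZ, from 2825 to 5239 in HZ against RZ and from 4275 to 6451 for any zone difference (each lowest without HZ 2). PZ against RZ fell to 259 without RZ 1, 315 without PZ 1 and 325 without PZ 2, MZ against PZ to 734 without PZ 1, 802 without PZ 2 and 421 without MZ 1, and HZ against MZ to 2902 without MZ 1 and 3281 without MZ 2. Lists called ranged from 11 to 17, from 7 to 15 (15 without PZ 2 and 10 without PZ 1), from 20 to 25 and from 16 to 18, and why the numbers rose without a PZ array was not tested. Of the 307 calls of genes 237 held without each of the arrays, as did 47 of the 61 calls of lists.

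The number of arrays limits the size of change that was detectable, with 76% of simulated changes of 1 on the log2 scale recovered in PZ against RZ and 8% of those of 0.5. Folds of genes with signals near the pseudocount of 7 are understated.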

Other observations

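Some signalling genes were chosen after their values were seen, all but Chrdl1 (a large rise of PZ against RZ) being outside the naming rule. Wnt4 rose from 90.85 ± 32.6 in RZ to 294.6 ± 158 in PZ (2.95-fold, adjusted p = 0.00076) and 1012 ± 484 in MZ (3.43-fold, adjusted p = 0.000355) and fell to 446 ± 211 in HZ (2.24-fold, adjusted p = 0.000387). Wnt5a also peaked in MZ, at 15.35 ± 3.18 in RZ, 35.3 ± 9.19 in PZ, 132.8 ± 29.3 in MZ and 68.45 ± 12.5 in HZ, as did the BMP antagonist Chrdl1, at 9.45 ± 10.8, 50.9 ± 20.8, 301.4 ± 162 and 78.55 ± 32.5. The WNT inhibitor Frzb was lowest in PZ, at 483.7 ± 41.9 in RZ, 57.85 ± 6.72 in PZ (7.57-fold lower, adjusted p = 1.98e-05), 240.4 ± 35.3 in MZ and 578.9 ± 56 in HZ. Another WNT inhibitor, Sfrp1, was highest in RZ at 390.6 ± 93.3 and stood at 44.05 ± 1.91 in HZ (7.68-fold lower, adjusted p = 6.15e-06). The hedgehog target Gli1 was 213.4 ± 82.7 in PZ and 65.5 ± 13.7 in MZ (2.96-fold lower, adjusted p = 0.00237), while Bmp4 rose 2.54-fold from 34.3 ± 1.27 to 98.25 ± 8.41 (adjusted p = 0.00881).

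PZ against RZ and HZ against MZ use different arrays. Of 382 genes lower in PZ than in RZ, 132 were higher in HZ than in MZ where 85.7 would be shared by chance, and of 245 genes higher in PZ, 119 were lower in HZ where 40 would be. Shared in the same direction were 65 lower (62.3 by chance) and 48 higher (55 by chance). The 3′ to 5′ ratio of Gapdh also fell from RZ to PZ and rose from MZ to HZ in both mice, while that of Actb fell in both steps. An effect of RNA quality on the opposed overlap was not tested.

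The 2 mice differed in 4501 of 12768 genes by limma's moderated test, which takes the 4 zones of an animal as its replicates and so compares 1 animal with 1 animal, 2334 higher in mouse 2 and 2167 higher in mouse 1. Over the 4 arrays of each mouse, Xist was 1591 ± 370 in mouse 1 and 40.25 ± 9.34 in mouse 2. The Y-linked Eif2s3y and Kdm5d were 2.65 ± 1.54 and 4.7 ± 2.76 in mouse 1 and 301.1 ± 45 and 94.78 ± 12.8 in mouse 2. The labels give no sex, but these values differ as between a female (mouse 1) and a male (mouse 2). Sex is thus confounded with the mouse. Malat1 was 3158 ± 859 in mouse 1 and 733 ± 250 in mouse 2. Among the control probe sets, the B1 repeat was 3503.2 ± 1952.3 in mouse 1 (1560.8 in RZ, 2085.3 in PZ, 5133 in MZ and 5233.9 in HZ) and 560.7 ± 82.2 in mouse 2 (619.4, 637.6, 463.7 and 522.2), the 3′ end of 18S rRNA 349.3 ± 289.2 (141.3, 265.5, 214 and 776.3) and 682 ± 147.6 (719, 871.2, 532.5 and 605.4), and the 5′ end of Actb 912 ± 195.5 and 452.9 ± 91.8.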
